A study of Mus musculus with 35 samples.

How the data were processed

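Histone mark ChIP-seq of C57BL/6 mouse bone marrow was analysed for H3K4me1, H3K4me3 and H3K27ac in 5 cell groups: lineage-negative HSPC of WT, Npm1c, Flt3-ITD and DM mice, and WT neutrophils. The series held 35 samples. Peak files existed for 30 libraries, 2 per group and mark, and these were read; 5 input samples had no file and were not used here. Per the submitters' processing notes, reads were aligned to mm10 with Bowtie2 2.1.0, duplicates were handled with Picard, and peaks were called per library with HOMER for H3K4me1 and H3K4me3 and with MACS2 for H3K27ac. Versions of Picard, HOMER and MACS2 and the calling thresholds are not given in the sources used here. The unit of the deposited files is other: peak coordinates in 3 columns (chromosome, start, end), with no score and no read count.

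Depth per library was therefore unknown and could not be separated from the number and width of peaks. HOMER peaks had a fixed width of 1000 bp, so H3K4me1 and H3K4me3 coverage moves in steps of about 1 peak, and many genes had no spread between replicates. Lists held from 102927 to 131205 peaks for H3K4me1, 30310 to 39320 for H3K4me3 and 21709 to 30150 for H3K27ac. Peaks off chromosomes 1 to 19, X and Y were left out of all comparisons.

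Gene positions came from a RefSeq table of GRCm38.p6, the same assembly as mm10, for 21883 protein-coding genes. That table gave gene spans without strand or exons, so the planned windows around transcription start sites were replaced by the gene span with 5 kb on each side for H3K4me3, and the span with 10 kb on each side was used for H3K4me1 and H3K27ac. Windows of neighbouring genes overlap. Overlaps and merging were computed with purpose-written interval code in Python 3.11.15 with NumPy 2.4.6 and pandas 2.3.3 instead of bedtools; figures were drawn with matplotlib 3.10.9.

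Similarity of lists was the base-pair Jaccard index, tested by comparing the mean within groups minus the mean between groups over all 105 pairings of the 8 HSPC libraries of a mark, or all 945 pairings of 10. Peaks of the 10 libraries of a mark were merged into regions. A region was present in a library when a peak overlapped it by at least 1 bp, gained when present in both libraries of the group and in neither library of the reference, and lost in the reverse case. With 2 libraries per group no region had a test of its own; as a yardstick, the same rule was applied to the 2 crossed splits, each side holding 1 library of either group. Distal sites were H3K4me1 regions without overlap of any H3K4me3 peak. A distal site with H3K4me1 in both WT libraries was activated when its H3K27ac was gained and inactivated when it was lost, whether or not the other group had H3K4me1 there; de novo sites gained both marks.

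For each gene, the base pairs of its window under peaks were summed per library as log2(bp + 500), for genes covered in at least 2 of the 10 libraries of a mark. limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend) fitted the 5 groups, with Benjamini-Hochberg adjustment per mark and comparison and a threshold of 0.05. There were 6 comparisons (each mutant and neutrophils against WT HSPC, DM against each single mutant) and the interaction of Npm1c and Flt3-ITD. No scaling between libraries was applied. Where a group had no peak at a gene its kb values are given without a fold. The interaction is given on the log2 scale there as well. Fixed gene lists, 17 in all, were tested with camera at a preset correlation of 0.01 and again with estimated correlation, adjusted over all lists, marks and comparisons: HOX cluster and HOX cofactor, stem and progenitor, primary granule and granulocyte-monocyte progenitor, mature neutrophil, monocyte and macrophage, erythroid, megakaryocyte, B-lymphoid, T and NK cell, eosinophil, basophil and mast cell, dendritic cell, STAT5 and MAPK feedback, AP-1 and immediate early, leukaemia-associated, housekeeping and other-tissue genes, and the 2 edited loci.

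Named genes were, among called genes whose 4 differences between single libraries had the same sign and leaving out clone names, the 5 largest rises and 5 largest falls for H3K27ac and 3 each for the other marks, with up to 4 members of each list for H3K27ac, called ones first, and the edited loci. Not every gene this rule took is printed. Shared calls between comparisons that use the same WT libraries were set beside n1 × n2 / N and beside simulated unchanged groups (20 simulations for genes, 100 draws for regions). Simulated lists were not held to the observed sizes. Their counts show what unchanged groups give, not what lists of the observed sizes share. For distal sites, a test added after the data were seen, N counted only sites in the WT state that the change requires. Groups, comparisons, tests, lists, the named-gene rule and the alternatives other than those added later were fixed before the data were examined.

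Alternatives were equal list lengths by widest peaks (H3K27ac only, since other widths are fixed), at least 50% coverage of a region, a Jaccard index of regions, a pseudocount of 2000 bp, genes covered in at least 1 library, centring on the median, a replicate block and leaving out each library. Chosen after seeing the data were equal list lengths by random peaks, the gene span without extension, robust eBayes, and a spread floor of 1 peak for H3K4me1 and H3K4me3.

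The code was tested on simulated data. For 5000 made regions, the 194 gained and 289 lost regions implied by the simulated lists were found, and 500 of 500 window sums were equal to a direct count. With changes of log2 1 and 2 added to 100 genes each in DM, 60% and 92% were recovered for H3K27ac, 31% and 79% for H3K4me1 and 41% and 69% for H3K4me3, with 12 of 164, 14 of 124 and 18 of 128 calls false.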

Results

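Peaks of H3K4me1 (enhancers and promoter flanks), H3K4me3 (promoters) and H3K27ac (active elements) were compared in lineage-negative bone marrow stem and progenitor cells (HSPC) of WT, Npm1c, Flt3-ITD and DM mice and in WT neutrophils. DM is read here as the double mutant of Npm1c and Flt3-ITD, which the labels do not spell out. Each group and mark had 2 libraries, which the series design states to be biological replicates. Gene values below are kb of peak inside a gene window, mean ± SD of 2 libraries.

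Averaged over pairs, peak lists grouped by genotype in each mark, and DM lists lay farther from WT than the lists of either single mutant. The base-pair Jaccard index (shared over combined length) averaged 0.507 within and 0.427 between HSPC genotypes for H3K4me1, 0.688 and 0.600 for H3K4me3, and 0.698 and 0.569 for H3K27ac. In each mark the true pairing gave the largest gap of all 105 pairings of the 8 HSPC libraries (exact permutation p = 0.00952) and of all 945 pairings of the 10 libraries (p = 0.00106). For H3K27ac the index with WT was 0.640 for Flt3-ITD, 0.588 for Npm1c, 0.512 for DM and 0.415 for neutrophils. DM lists shared more with Flt3-ITD (0.600) than with Npm1c (0.474). Single pairs departed from this grouping. For H3K4me1 the 2 Npm1c lists shared 0.444 with each other. Npm1c replicate 2 shared more than that with the WT lists (0.534 and 0.548), and Npm1c replicate 1 less (0.435 and 0.432). For H3K27ac DM replicate 1 shared 0.634 with Flt3-ITD replicate 1 and 0.614 with DM replicate 2. For H3K4me3 WT replicate 1 shared 0.699 with Npm1c replicate 2 and 0.693 with WT replicate 2.

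**Figure D1:**
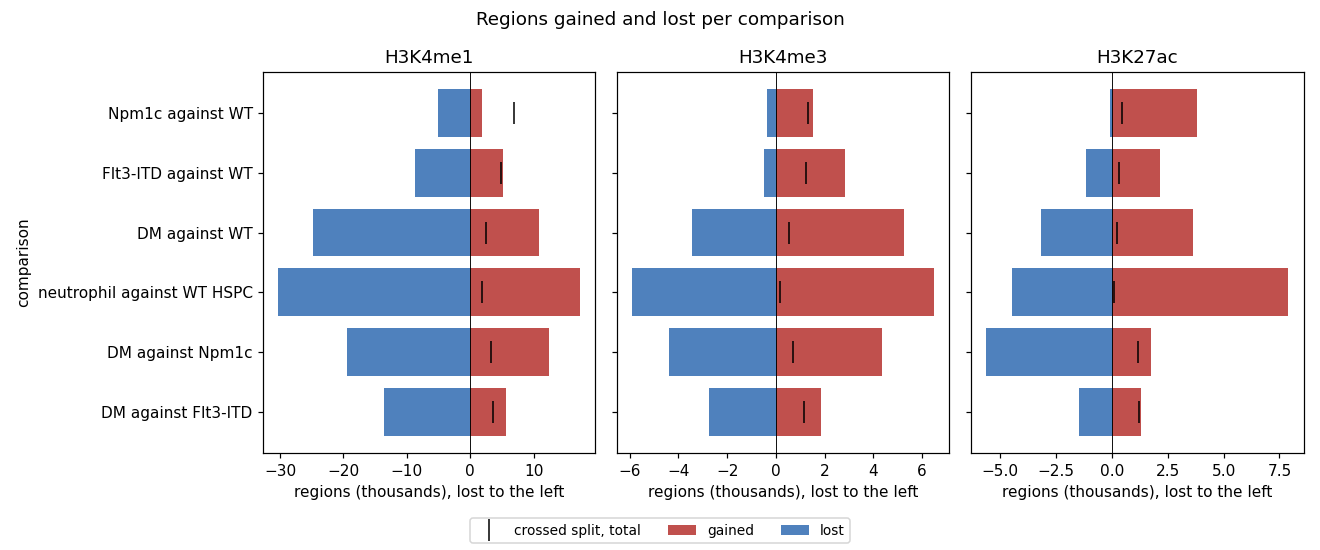
Regions gained and lost in each comparison, per mark. Ticks give the larger total of the 2 crossed splits of the same 4 libraries.

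H3K27ac covered 15.2 ± 0.0580 Mb in WT, 23.7 ± 0.333 Mb in Npm1c, 17.5 ± 1.26 Mb in Flt3-ITD, 16.9 ± 4.84 Mb in DM and 16.3 ± 0.411 Mb in neutrophils. A test of 2 against 2 libraries cannot give an exact p below 0.333, the value for Npm1c, Flt3-ITD and neutrophils (1 for DM); over all pairings p was 0.111. Exact permutation of peak numbers over all pairings gave p = 0.281 for H3K4me1, 0.622 for H3K4me3 and 0.0709 for H3K27ac. The median width of H3K27ac peaks was 536 ± 8.49 bp in WT and 554 ± 15.6 bp in Npm1c (exact permutation p = 0.148 over all pairings).

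HOXA genes and their cofactor gene Meis1, which sustain stem cell self-renewal and mark NPM1-mutant leukaemia, had the largest H3K27ac rises in Npm1c cells. Hoxa9 (6:52223097-52227370) rose from 1.58 ± 0.146 to 20.0 ± 0.226 kb (log2 change 3.31; limma, Benjamini-Hochberg adjusted p = 0.000188), Hoxa10 from 1.07 ± 0.177 to 13.7 ± 0.0170 kb (3.18) and Hoxa7 from 1.49 ± 0.0212 to 15.6 ± 0.0686 kb (3.02). Meis1 (11:18880428-19019651) rose from 0.486 ± 0.315 to 9.07 ± 2.25 kb (3.30; adjusted p = 0.00915), and Slc8a1, a sodium-calcium exchanger gene, had no peak in WT and 3.00 ± 0.151 kb in Npm1c. Windows of neighbouring Hoxa genes overlap, so these calls are not independent. Over the whole Hoxa cluster, a sum chosen after the values were seen, H3K27ac went from 2.22 ± 0.236 to 23.6 ± 0.251 kb. The cluster already carried H3K4me1 (18.5 ± 0.707 in WT, 18.0 ± 2.83 kb in Npm1c) and H3K4me3 (17.8 ± 0.0318 and 16.2 ± 0.799 kb). The Hoxb cluster had 0.496 ± 0.00778 kb of H3K27ac in WT and 4.0 ± 0.221 kb in Npm1c, and the Hoxc and Hoxd clusters had 0 kb in every group.

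Stem cell regulators followed. The receptor genes Kit (1.18 ± 0.0389 to 5.05 ± 0.528 kb, log2 1.72) and Flt3 (0.830 ± 0.158 to 4.24 ± 0.559 kb, 1.83) and the transcription factor gene Gata2 (1.38 ± 0.172 to 8.46 ± 0.0106 kb, 2.25; limma, Benjamini-Hochberg adjusted p = 0.0305) rose. Of the 17 HOX and HOX cofactor genes tested, 13 rose, 0 fell and 4 did not pass (15 rises when adjusted over the list alone), with a median log2 change of 2.18 (camera, Benjamini-Hochberg adjusted p = 8.45e-15). Windows of neighbouring Hox genes hold the same peaks, so neither the count nor the camera p rests on 17 separate genes. That limit applies to the HOX list in every comparison. Stem and progenitor genes had 10 rises in 21 (16 over the list alone; median 0.85, camera adjusted p = 0.00433), and AP-1 and immediate early genes had 10 in 19 (13 alone; 0.51, adjusted p = 0.0161), among them Fos, Fosb, Nr4a2 and Atf3. Megakaryocyte genes had 5 rises in 14 (9 alone): the platelet chemokine genes Ppbp and Pf4 had no H3K27ac peak in any other group and 1.09 ± 0.218 and 0.969 ± 0.0537 kb in Npm1c, and the integrin genes Itga2b and Itgb3 rose too. Of the 5 eosinophil, basophil and mast cell genes tested 3 rose (Hdc, Ccr3, Ms4a2), as did 6 of 28 leukaemia-associated genes (Runx1, Dot1l, Idh2 and Cd96 with the largest rises), 4 of 13 dendritic cell genes, 4 of 23 STAT5 and MAPK feedback genes (Spry1, Ccnd2, Dusp5, Spred2), 3 of 8 T and NK cell genes and 2 of 16 erythroid genes (Car1, Rhag). The housekeeping genes Ywhaz, Polr2a and Tbp, the B-lymphoid genes Cd22 and Rag2, and Cebpe rose too, none of them called after centring on the median. Of all genes tested 17.7% were called, so counts near that share do not set a list apart. Of 21 mature neutrophil genes 1 rose (Il1b). In WT and Npm1c 11 had no H3K27ac peak in any library, so their median of 0 (camera adjusted p = 2.58e-06, direction down; 0.947 with lists of equal length drawn at random) does not set them apart from other genes.

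Across all 13633 genes tested for H3K27ac in Npm1c, 2412 rose and 3 fell, and the median gene shifted by 0.36 on the log2 scale. With each library centred on its median, 78 rose and 5 fell, 81 of them called both ways. The HOX list kept 12 rises in 17 (median 1.78) and the stem and progenitor list 3 in 21 (Meis1, Flt3, Kit), and Ppbp and Pf4 stayed called. The other counts above became 2 of 14 megakaryocyte and 1 of 13 dendritic cell genes, and 0 of 19 AP-1, 28 leukaemia-associated, 23 STAT5 and MAPK feedback, 16 erythroid, 8 T and NK cell and 5 eosinophil, basophil and mast cell genes. Of the 44 called genes that the naming rule took, 33 lost their call. Calls ended with centring for Gata2 (log2 2.25 before and 1.85 after; limma, Benjamini-Hochberg adjusted p = 0.127 after), Atf3 (1.67 and 1.27), Spry1 (1.47 and 1.07; adjusted p = 0.0524), Itgb3 (1.44 and 1.04), Itga2b (1.21 and 0.81) and Runx1 (1.13 and 0.72). They also ended for Hdc, Ccr3, Ms4a2, Il1b, Fosb, Nr4a2, Fos, Car1, Cd96, Ccnd2, Dot1l, Idh2, Rhag, Dusp5 and Spred2 (1.23 to 0.18 after centring). All of these values stayed above 0 without passing, so a rise beyond the general one is left open for them. With lists of equal length drawn at random, a choice made after seeing the data, 88 genes rose and 120 fell. There the HOX list had 9 rises in 16 (median 1.95) and the stem and progenitor list 2 in 21 (0.53). Hoxa9, Hoxa7, Meis1, Slc8a1, Gata2, Ppbp and Pf4 stayed called and Hoxa10, Flt3 and Kit did not. Of the 43 called genes that the naming rule took, 11 stayed called and 2 turned in sign. The count of genes was 1395 with a replicate block, which ended the calls at Itgb3, Spred2 and Runx1, and 1093 with lists of equal length made of the widest peaks, where 1710 regions differed. Npm1c gained 3822 and lost 95 H3K27ac regions against at most 476 in a crossed split of the same 4 libraries. The widest gained ones lay in Rnf220, Adgrg1 and Zfp217. Hoxa9 and Hoxa7 stayed called without any of the libraries, while without WT replicate 1, WT replicate 2, Npm1c replicate 1 or Npm1c replicate 2 the count of genes went to 9, 5, 1252 or 776. Meis1, Slc8a1, Flt3, Kit, Ppbp and Pf4 needed both WT libraries. The AP-1 list did not pass without Npm1c replicate 2 (camera adjusted p = 0.283), with random peaks (0.732) or with the gene span without extension (0.462).

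H3K4me1 and H3K4me3 calls in Npm1c were fewer than those of H3K27ac as counted without centring; after centring H3K4me3 had 221 and H3K27ac 83. The Fc epsilon receptor gene Fcer1a, read on mast cells and basophils, had no H3K4me1 in WT and 2 ± 0 kb in Npm1c (limma, Benjamini-Hochberg adjusted p = 2.67e-06). Olfr1404, whose window overlaps it, and Clrn1 also gained a peak, and Sox14, Nxf7 and Asdurf lost theirs. Of 17377 genes 20 rose and 38 fell (shift of the median gene -0.13), and none was called after centring, with robust eBayes or with a spread floor of 1 peak. The count was 35 with random peaks and 153 with the gene span without extension, and the 6970 regions that differed (1885 gained, 5085 lost) hardly exceeded a crossed split (6834). For H3K4me3, 156 genes rose and 65 fell of 16134. Acr, Adamts16 and Aoc1 gained 1 kb, and Apba2, S100a7a and Asprv1 lost all coverage. Of these 6 calls 3 ended with a spread floor of 1 peak and 3 with a pseudocount of 2000 bp. In regions, 1514 were gained and 359 lost (crossed splits up to 1336). Mature neutrophil genes had a median H3K4me3 change of -0.75 (2 falls in 24; camera, Benjamini-Hochberg adjusted p = 1.01e-05). Without Npm1c replicate 2 these counts of genes went to 1459 and 1038, without WT replicate 1 to 164 and 832, without WT replicate 2 to 128 and 493, and without Npm1c replicate 1 to 204 and 474. Calls ended for Sox14 and Adamts16 without WT replicate 1, WT replicate 2 or Npm1c replicate 1, for Adamts16 also without Npm1c replicate 2, and for Nxf7, Apba2 and S100a7a without Npm1c replicate 1.

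In Flt3-ITD cells the interferon regulatory factor gene Irf8, which directs monocyte and dendritic cell fate, gained H3K27ac. Irf8 (8:120736358-120756694) had no peak in WT and 3.55 ± 0.274 kb in Flt3-ITD (limma, Benjamini-Hochberg adjusted p = 0.0268), and the widest gained region of the comparison lay inside it (8:120736534-120740758). Mef2c, a myeloid and lymphoid progenitor factor gene, rose from 1.78 ± 0.214 to 10.4 ± 0.964 kb (log2 2.26; adjusted p = 0.0268), the interferon-induced Ifitm2 from 0.241 ± 0.0311 to 2.67 ± 0.00141 kb (2.1) and the RAS GTPase activator gene Rasa4 from 0.602 ± 0.000707 to 3.21 ± 0.443 kb (1.75). Upk3bl, whose window overlaps that of Rasa4, had no peak in WT and 2.23 ± 0.163 kb in Flt3-ITD, and Cd96 had 0 and 0.456 ± 0.0488 kb. The colipase genes Clps and Clpsl2, which share a window, went from 0.633 ± 0.0636 to 0 kb and Slc22a29 from 0.436 ± 0.0332 to 0 kb. The Flt3 locus itself went from 0.830 ± 0.158 to 4.84 ± 0.765 kb without passing (log2 2.0; adjusted p = 0.0535), and Npm1 did not pass in any HSPC group. Peak coverage at Npm1 or Flt3 does not show either mutation and checks no genotype.

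Only 11 genes rose and 3 fell for H3K27ac in Flt3-ITD (limma, Benjamini-Hochberg), while 2094 had an unadjusted p below 0.05. The median gene shifted by 0.12, and after centring 114 rose and 66 fell, among them Flt3, Hoxa9, Meis1, Spry1 and Mcl1 up and Car1 down, without Cd96. HOX genes had 0 calls in 17 but 8 rises over the list alone (median 0.67; camera, Benjamini-Hochberg adjusted p = 7.21e-05), stem and progenitor genes 0 in 21 and 3 (0.43, adjusted p = 0.0171), and erythroid genes 0 in 16 but 4 falls over the list alone (-0.38, adjusted p = 5.11e-09). Megakaryocyte genes had 0 calls and a median of 0 (adjusted p = 0.0435, direction down). Among 16 primary granule and granulocyte-monocyte progenitor genes Irf8 rose, and among 28 leukaemia-associated genes Cd96. Flt3-ITD gained 2141 and lost 1171 H3K27ac regions (crossed splits up to 346). The 14 calls fell to 0 without WT replicate 1, WT replicate 2 or Flt3-ITD replicate 1, to 7 without Flt3-ITD replicate 2, and to 0 with a pseudocount of 2000 bp. They numbered 1 with a replicate block (Upk3bl) or with random peaks (Mef2c), 8 with robust eBayes, 9 with lists of equal length made of the widest peaks and 68 with the gene span without extension, so the Irf8 call rests on the settings used. The camera adjusted p was 0.179 for the stem and progenitor list without Flt3-ITD replicate 2 and 0.292 and 0.0733 for the megakaryocyte list without Flt3-ITD replicate 1 and WT replicate 2; the latter list did not pass with centring (0.132) or random peaks (0.222) either.

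H3K4me1 in Flt3-ITD rose at the phospholipase gene Pla2g4f (0 in WT, 4.50 ± 0.707 kb), Aadacl3 and Hpgd (0 and 2.50 ± 0.707 kb each). It was lost at the heparan sulfate gene Ndst3 (9.5 ± 2.12 to 0 kb; limma, Benjamini-Hochberg adjusted p = 0.000446), the erythroid carbonic anhydrase gene Car1 (8.50 ± 0.707 to 0 kb; adjusted p = 6.78e-05) and the X-linked clotting factor gene F8 (4.50 ± 0.707 to 0 kb). In all, 92 genes rose and 204 fell; 5168 regions were gained and 8664 lost (crossed splits up to 4839). The erythroid list had a median of -0.28 (1 fall in 18; camera, Benjamini-Hochberg adjusted p = 0.0173). The count of genes was 445 without Flt3-ITD replicate 2, 189 (70 up, 119 down) after centring and 196 with a replicate block. It was 104 with random peaks, which ended the F8 call, 62 with robust eBayes and 86 with a spread floor of 1 peak, which ended the calls at Aadacl3 and Hpgd. H3K4me3 rose at the bradykinin receptor gene Bdkrb2, Pfpl and Slamf8 (0 in WT, 2 ± 0 kb each) and was lost at Il2rb, S100a7a and Asprv1. 367 genes rose and 73 fell, 2845 regions were gained and 483 lost (crossed splits up to 1238), and mature neutrophil genes had a median of -0.88 (2 falls in 24; camera adjusted p = 2.15e-06). Without WT replicate 1, WT replicate 2, Flt3-ITD replicate 1 or Flt3-ITD replicate 2 the H3K4me3 count was 986, 719, 874 or 754, and it was 289 with random peaks. The Il2rb call ended without each of these libraries but WT replicate 1, and with random peaks, a replicate block, a pseudocount of 2000 bp or the gene span without extension.

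**Figure D2:**
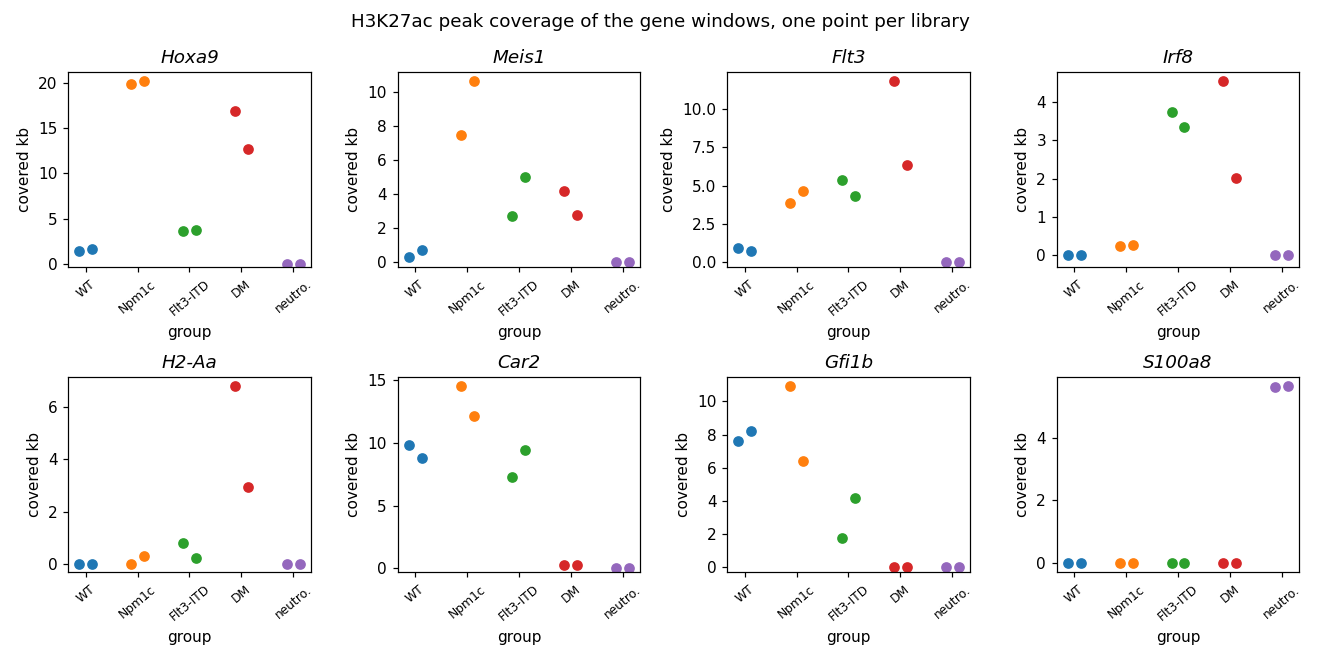
H3K27ac coverage of 8 gene windows in each library. S100a8 marks mature neutrophils and Car2 and Gfi1b erythroid and megakaryocyte progenitors.

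DM cells lost H3K27ac at erythroid genes. The repressor gene Gfi1b (2:28609450-28621982), needed for red cell and platelet formation, went from 7.89 ± 0.425 kb in WT to 0 in DM (limma, Benjamini-Hochberg adjusted p = 0.00133), the water channel gene Aqp1 from 5.34 ± 0.270 to 0 kb and the rhesus-associated Rhag from 2.22 ± 0.143 to 0 kb. Car2 (3:14886269-14900770) fell from 9.33 ± 0.680 to 0.265 ± 0.0106 kb (log2 -3.68; adjusted p = 9.87e-05), the erythroid ankyrin gene Ank1 from 5.78 ± 0.263 to 0.511 ± 0.245 kb (-2.66) and Tal1, the stem and erythroid factor gene, from 6.85 ± 0.145 to 1.44 ± 0.414 kb (-1.94). Erythroid genes had 13 falls in 16, 0 rises and 3 not passing (13 falls over the list alone; median -1.73; camera, Benjamini-Hochberg adjusted p = 3.16e-14). Megakaryocyte genes had 3 falls (Gfi1b, Gp9, Vwf) and 1 rise (Itgb3) in 14 and did not pass as a list (median -0.26; camera adjusted p = 0.0861). Further falls were at the protease gene Bmp1 (6.05 ± 0.272 to 0 kb), the lipase gene Mgll (6.68 ± 0.0445 to 0.101 ± 0.143 kb, -3.60), and the leukaemia-associated Trib2 (3.25 ± 0.0445 to 0 kb) and Prdm16 (1.79 ± 0.163 to 0 kb).

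In DM 5 of 13 dendritic cell genes gained H3K27ac, among them Flt3 and the class II pathway genes H2-Aa, H2-Ab1 and Cd74. The class II gene H2-Aa and the dendritic maturation marker Cd83 had no peak in WT and 4.86 ± 2.73 and 4.78 ± 1.18 kb in DM (limma, Benjamini-Hochberg adjusted p = 0.00419 and 0.00106). H2-Ab1 rose from 0.360 ± 0.0537 to 4.74 ± 1.27 kb (log2 2.59), the invariant chain gene Cd74 from 0.298 ± 0.0877 to 4.92 ± 0.773 kb (2.76) and Flt3 from 0.830 ± 0.158 to 9.08 ± 3.90 kb (2.79; adjusted p = 0.00186). No dendritic cell gene fell (8 rose and 1 fell over the list alone; median 0.96; camera, Benjamini-Hochberg adjusted p = 0.00031), and of 11 monocyte and macrophage genes 5 rose (7 alone; 1.38, adjusted p = 0.00405), among them Csf1r, Klf4, Cd14 and Ms4a6c. The chemotactic receptor gene Gpr183, the receptor kinase gene Ror1 and Stxbp6 had no peak in WT and 4.12 ± 1.37, 4.01 ± 0.556 and 5.39 ± 1.66 kb in DM. Irf8 had 3.29 ± 1.80 kb and the STAT5 target Socs2 3.48 ± 1.53 kb in DM, each with 0 in WT.

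The HOXA programme of the Npm1c cells was present in DM: Hoxa9 rose to 14.8 ± 3.02 kb (log2 2.87; limma, Benjamini-Hochberg adjusted p = 0.000214), Hoxa7 to 12.1 ± 2.13 kb (2.65), Hoxa10 to 8.81 ± 2.38 kb (2.55), Hoxa6 from 0.522 ± 0.0127 to 5.62 ± 0.835 kb (2.57) and Meis1 to 3.48 ± 0.996 kb (2.03). HOX genes had 8 rises in 17 (10 over the list alone; median 1.04; camera, Benjamini-Hochberg adjusted p = 4.15e-07). Stem and progenitor genes split, with 4 rises and 5 falls in 21. Gata2 went from 1.38 ± 0.172 to 0 kb. AP-1 and immediate early genes had 5 rises in 19 (Atf3, Nr4a1, Fos and Fosb among them; 6 alone; median 0.35, adjusted p = 0.00732). STAT5 and MAPK feedback genes had 3 rises and 2 falls in 23 (Spry1 up, the RAS pathway brakes Spry2 and Spred1 down) and leukaemia-associated genes 5 and 2 in 28 (Bcl2, 1.10 ± 0.179 to 6.77 ± 3.81 kb, and Cd33 up). Primary granule genes had 2 rises (Irf8, Csf1r) and 1 fall (Fcnb) in 16, mature neutrophil genes 3 rises in 21 (Mmp25, Il1b, Csf3r; median 0), T and NK cell genes 1 rise (Il2rb) and 1 fall (Cd247) in 8, genes of other tissues 1 fall in 4 (Gfap), and B-lymphoid (11), eosinophil, basophil and mast cell (5) and housekeeping genes (15; median 0.05) none.

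Across genes, H3K27ac in DM rose at 946 and fell at 822 of 13633, and 3645 regions were gained and 3170 lost (crossed splits up to 247). The widest lost regions lay in Zfpm1 (8:122282106-122287013), the gene of the GATA1 cofactor, and Aqp1, and near Gfi1b, and the widest gained ones included Gpr183. Without WT replicate 1, WT replicate 2 or DM replicate 2 the count of genes was 213, 295 or 2713. Car2, Gfi1b, Aqp1, Rhag, Hoxa9, Flt3, Cd83, H2-Aa, H2-Ab1, Socs2, Trib2 and Prdm16 stayed called each time, whereas Gata2, Csf1r, Klf4, Cd14, Cd74, Ank1, Gp9, Bcl2, Spry1 and Spry2 did not without WT replicate 1 or WT replicate 2. Neither did Fosb, Atf3, Cd33, Itgb3, Vwf, Fcnb, Il1b, Csf3r, Ms4a6c, Spred1, Il2rb, Cd247 and Gfap, nor, without WT replicate 1, Meis1, Nr4a1 and Fos. Without DM replicate 1 Gata2, Fosb, Atf3, Csf1r, Klf4, Bcl2, Itgb3, Il2rb and Ms4a6c also lost their calls, and without DM replicate 2 Gata2, Fosb, Atf3, Vwf, Cd247, Gfap and Spred1. The AP-1 list did not pass without DM replicate 2 (camera adjusted p = 0.104). The count after centring was 1577 up and 1478 down. With random peaks it was 308 up and 296 down, and of the 50 called genes that the naming rule took 28 stayed called. Aqp1, Tal1, Hoxa10, Irf8, Csf1r, Klf4, Cd14, Itgb3, Vwf, Spry1, Spry2, Spred1, Atf3, Fos, Fosb, Cd33, Il1b, Csf3r, Fcnb, Il2rb, Cd247 and Gfap lost their calls there. Gata2 lost its call with a replicate block or a pseudocount of 2000 bp.

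H3K4me1 fell more widely than it rose in DM, at 2819 against 332 of 17377 genes, with the median gene shifted by -0.21; after centring 959 rose and 1539 fell. The ephrin receptor gene Epha4 (15 ± 1.41 to 0 kb; limma, Benjamini-Hochberg adjusted p = 0.000201), Ndst3 (9.5 ± 2.12 to 0 kb) and Car1 (8.50 ± 0.707 to 0 kb) lost all coverage, and Malrd1 (0 to 12.5 ± 2.12 kb), the potassium channel subunit gene Kcnmb2 (0 to 8 ± 2.83 kb) and Col6a6 (0 to 6.5 ± 0.707 kb) gained most. Erythroid genes had 13 falls in 18 (15 over the list alone; median -1.19; camera, Benjamini-Hochberg adjusted p = 1.76e-05), megakaryocyte genes 8 falls and 1 rise in 16 (-0.66, adjusted p = 0.0472) and dendritic cell genes 4 rises and 1 fall in 17 (0.18, adjusted p = 0.000147). H3K4me3 rose at 720 and fell at 597 of 16134 genes: the chemokine receptor gene Ccr6 (0 to 4.50 ± 0.707 kb), Upk1b and Dthd1 rose most, Esrrg went from 4 ± 0 to 0 kb, Hoxd3 fell from 5.15 ± 0.706 to 0.5 ± 0.707 kb (log2 -2.70) and the mast cell carboxypeptidase gene Cpa3 went from 2.50 ± 0.707 to 0 kb. Eosinophil, basophil and mast cell genes had 6 H3K4me3 falls in 12 (8 falls and 1 rise over the list alone; median -1.95; camera adjusted p = 0.00185). Mature neutrophil genes had a median H3K4me3 change of -0.81 after centring, with 4 falls and 0 rises in 24 (camera, Benjamini-Hochberg adjusted p = 0.000711). They were lower in both single mutants as well, and all these comparisons share the WT libraries. Regions gained and lost numbered 10793 and 24774 for H3K4me1 (crossed splits up to 2418) and 5253 and 3453 for H3K4me3 (up to 526). Without WT replicate 1, WT replicate 2 or DM replicate 1 the H3K4me1 count of genes was 1902, 1550 or 1896, and with random peaks 1003. The H3K4me3 count was 593 with random peaks and 2131 with a spread floor of 1 peak. The calls at Col6a6 and Ccr6 ended without WT replicate 1, WT replicate 2, DM replicate 1 or DM replicate 2, and that at Hoxd3 without WT replicate 1 or WT replicate 2. Random peaks or a replicate block ended those at Ccr6 and Hoxd3. Of 466 genes called for both H3K4me1 and H3K27ac 417 moved the same way. Most genes called for one mark were not called for the other.

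No list call in any comparison or mark held when camera estimated the correlation between genes from the 10 libraries instead of taking it as 0.01 (lowest adjusted p = 0.600), so each camera p here rests on that preset value.

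**Figure D3:**
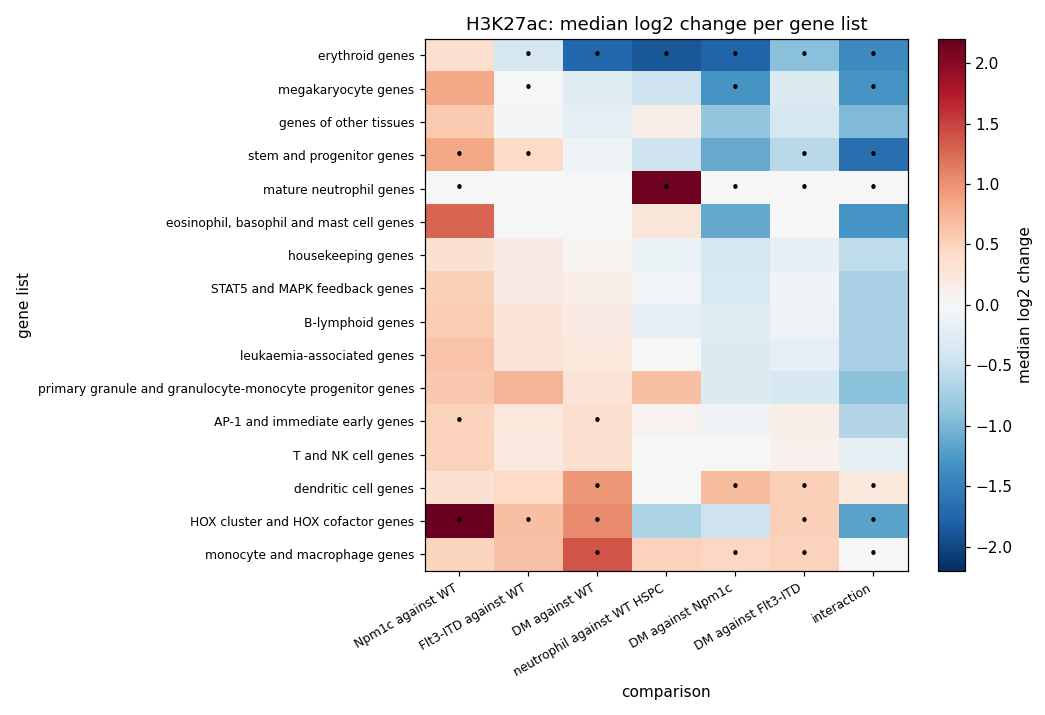
Median log2 H3K27ac change of the fixed gene lists in each comparison. Dots mark camera adjusted p below 0.05 with the preset correlation.

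Against Npm1c cells, DM cells had less H3K27ac at erythroid genes and more at 5 of 13 dendritic cell genes. Car2 fell from 13.3 ± 1.70 to 0.265 ± 0.0106 kb (log2 -4.17; limma, Benjamini-Hochberg adjusted p = 3.95e-05), Kit from 5.05 ± 0.528 to 0.466 ± 0.159 kb (-2.53), the netrin gene Ntn4 from 15.3 ± 4.78 to 0.377 ± 0.209 kb (-4.16) and Mgll from 9.22 ± 3.14 to 0.101 ± 0.143 kb (-4.0), and Gata2 went from 8.46 ± 0.0106 to 0 kb and Gfi1b from 8.67 ± 3.19 to 0 kb. Cd83 rose from 0.102 ± 0.144 to 4.78 ± 1.18 kb (3.13), H2-Aa from 0.149 ± 0.211 to 4.86 ± 2.73 kb (2.98), Stxbp6 (2.78) and Cd74 (2.72) rose with them, and Socs2 went from 0 to 3.48 ± 1.53 kb. Erythroid genes had 15 falls in 16 (median -1.77; camera, Benjamini-Hochberg adjusted p = 3.02e-07), megakaryocyte genes 10 falls in 14 (-1.30, adjusted p = 0.0189), stem and progenitor genes 12 falls and 2 rises in 21 (camera adjusted p = 0.240), and HOX genes 9 falls in 17 (camera adjusted p = 0.406), led by Hoxb5 (2.64 ± 0.329 to 0 kb), Hoxb6, Hoxb3 and Hoxb4. Dendritic cell genes had 5 rises and 1 fall in 13 (0.69, adjusted p = 1.48e-06) and monocyte and macrophage genes 2 rises and 1 fall in 11 (0.46, adjusted p = 6.08e-05). In all 410 genes rose and 4212 fell, with the median gene shifted by -0.31; after centring 1778 rose and 1915 fell, Car2, Kit, Gata2 and Cd83 among them. The count was 2648 without Npm1c replicate 1 and 1237 with random peaks, which ended the Kit call. The megakaryocyte list did not pass without DM replicate 1 (camera adjusted p = 0.160), with the widest peaks (0.0681) or with the gene span without extension (0.0716). DM gained 1765 and lost 5602 H3K27ac regions (crossed splits up to 1192), 12491 and 19497 of H3K4me1 (up to 3346) and 4368 and 4371 of H3K4me3 (up to 721). H3K4me1 rose at 538 and fell at 2096 genes (1383 and 1648 after centring; Lrrc4c, Kcnmb2 and Arnt2 up most, Epha4, Thsd7b and Piezo2 down most; 1525 and 1679 in all without DM replicate 1 or 2, 1248 with random peaks), and H3K4me3 rose at 612 and fell at 700 (659 with random peaks, 2040 with a spread floor of 1 peak; Upk1b, Dthd1 and Fam155a up, Esrrg, Ms4a2 and Pdzph1 down). Calls at Lrrc4c, Arnt2, Fam155a, Ms4a2 and Pdzph1 ended without DM replicate 1, all of them but Lrrc4c without DM replicate 2, Lrrc4c, Fam155a and Ms4a2 without Npm1c replicate 1, and Fam155a and Ms4a2 without Npm1c replicate 2.

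Against Flt3-ITD cells, DM cells had more H3K27ac at HOXA genes and less at erythroid genes. Hoxa9 rose from 3.69 ± 0.0530 to 14.8 ± 3.02 kb (log2 1.85; limma, Benjamini-Hochberg adjusted p = 0.00192), Hoxa7 (1.83) and Hoxa10 (1.69) alike, and Hoxa11 had 0 in Flt3-ITD and 1.91 ± 0.569 kb in DM. Cd83 rose from 0.144 ± 0.204 to 4.78 ± 1.18 kb (3.05), H2-Aa (2.33), the NF-kappaB inhibitor gene Tnip3 (2.13) and Socs2 (2.11) rose, and Cttnbp2nl went from 0 to 2.47 ± 0.851 kb. Car2 fell from 8.38 ± 1.52 to 0.265 ± 0.0106 kb (-3.53), its neighbour Car3 with it (-2.69), and Aqp1 (3.47 ± 0.713 kb), Gfi1b (2.96 ± 1.71 kb) and Dach1 (3.11 ± 0.288 kb) went to 0 kb. HOX genes had 7 rises in 17 (median 0.53; camera, Benjamini-Hochberg adjusted p = 4.12e-07), erythroid genes 7 falls in 16 (13 over the list alone; -0.93, adjusted p = 2.63e-10), stem and progenitor genes 6 falls and 1 rise in 21 (-0.61, adjusted p = 0.00901) and dendritic cell genes 3 rises in 13 (6 alone; 0.52, adjusted p = 1.17e-05). In all 86 genes rose and 252 fell (366 and 434 after centring). The count was 88 without Flt3-ITD replicate 2, 1751 and 568 without DM replicate 1 and 2, 187 with a replicate block, and 192 with a pseudocount of 2000 bp, which ended the Gfi1b call. It was 91 with random peaks, where Hoxa9, Hoxa7, Hoxa10, Hoxa11, H2-Aa, Tnip3, Aqp1 and Dach1 lost their calls. The stem and progenitor list did not pass without DM replicate 2 (camera adjusted p = 0.0682) or with random peaks (0.126). DM gained 1330 and lost 1478 H3K27ac regions (crossed splits up to 1209), 5695 and 13621 of H3K4me1 (up to 3636) and 1865 and 2749 of H3K4me3 (up to 1160). H3K4me1 rose at 167 and fell at 1446 genes (median gene -0.16; 297 and 582 after centring, 908 in all without DM replicate 1 and 335 with random peaks; Malrd1, Lrrc4c and Syt1 up, Epha4, Frem3 and Ghrhr down), and H3K4me3 rose at 327 and fell at 585 (558 with random peaks; Klk15, Tmem178 and Cd300c2 up, Irx4, Esrrg and Hoxd3 down). Calls ended without Flt3-ITD replicate 2 at H2-Aa, Tnip3, Malrd1, Lrrc4c, Tmem178 and Hoxd3, without Flt3-ITD replicate 1 at Tnip3, Tmem178, Irx4 and Hoxd3, and without DM replicate 1 or DM replicate 2 at Malrd1, Lrrc4c, Tmem178 and Irx4.

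At the genes called here, the change in DM differed from the sum of the log2 changes in the single mutants. Which genes were called depended strongly on the settings, as given below. The interaction (DM - Npm1c - Flt3-ITD + WT) was negative at Gata2 (log2 -4.45; limma, Benjamini-Hochberg adjusted p = 0.015), Car2 (-4.02; adjusted p = 0.000658), Meis1 (-3.40), Armc2 (-3.39), Kit (-3.08), Hoxb5 (-3.31), Hoxb3 (-2.55) and Hoxb4 (-2.38). All of these but Car2 rose in Npm1c, and all of them had less H3K27ac in DM than in Npm1c. It was positive at Cd83 (2.81), Cttnbp2nl (2.54), Socs2 (2.11), Cd74 (2.07) and Ctnnd2 (1.94), of which Cttnbp2nl and Ctnnd2 had peaks in DM alone among the HSPC groups. For H3K27ac it was positive at 63 genes and negative at 2389. The median gene stood at -0.46, and after centring the counts were 198 and 341, with Gata2, Car2, Meis1, Kit, Cd83 and Socs2 among them. For H3K4me1 it was positive at 151 and negative at 431 genes (Syt1, Dapl1 and Olfr1258 up, Epha4, Frem3 and Garem1 down) and for H3K4me3 at 316 and 610 (Il2rb, Cd300c2 and Cd300ld4 up, Ms4a2, Pdzph1 and Aoc1 down). Without WT replicate 1, WT replicate 2, Npm1c replicate 1, Flt3-ITD replicate 2, DM replicate 1 or DM replicate 2 the H3K27ac count was 77, 33, 1378, 468, 6131 or 1572. Car2, Kit, Rhag and Trib2 stayed called each time, Cd83, Gata2, Meis1, Armc2, Hoxb3, Hoxb4, Hoxb5, Socs2, Cd74 and Ctnnd2 not without WT replicate 1 or WT replicate 2, nor Cttnbp2nl without WT replicate 2. With random peaks the H3K27ac count was 81, and 7 of 46 called genes that the naming rule took stayed called. Gata2, Car2, Meis1, Cd83, Cttnbp2nl and Socs2 did, and Kit, Armc2, Hoxb3, Hoxb4, Hoxb5, Cd74, Ctnnd2, Rhag and Trib2 did not. With a replicate block the count was 1378, and 12 of 47 such calls ended, that at Cd74 among them. Socs2, Cd74 and Ctnnd2 also needed both Npm1c libraries, Armc2, Cd74 and Ctnnd2 Flt3-ITD replicate 2, and Cd74 both DM libraries. The H3K4me1 count was 172 after centring, 190 with robust eBayes, 208 with random peaks and 223 with a spread floor of 1 peak, and the H3K4me3 count 551 with random peaks and 443 with that floor. Without Npm1c replicate 2 the H3K4me1 count was 1526 and the H3K4me3 count 1745, and the latter was 1502 without WT replicate 1 and 1460 without Flt3-ITD replicate 1. Calls at Dapl1 and Frem3 for H3K4me1 and Ms4a2 for H3K4me3 ended without Npm1c replicate 1, Npm1c replicate 2, Flt3-ITD replicate 1 or Flt3-ITD replicate 2, those at Dapl1 and Ms4a2 also without DM replicate 1 or DM replicate 2 and that at Frem3 without WT replicate 1 or WT replicate 2. The Pdzph1 call ended without WT replicate 1, WT replicate 2, Flt3-ITD replicate 2, DM replicate 1 or DM replicate 2.

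Most regions gained in DM had a peak in at least 1 single-mutant library, and most regions lost in DM were missing from at least 1. Of the H3K27ac regions lost in DM, 1099 were also lost in Flt3-ITD (1171 in all), against 91.9 for independent lists and 154 in simulated unchanged groups that share the WT libraries; of those gained, 1258 were gained in Flt3-ITD (193 and 459) and 799 in Npm1c (345 and 462). Simulated lists were not held to the observed sizes: for lost regions those of Npm1c and DM shared 153, although Npm1c lost 95. Only the values for independent lists take list size into account. Part of each excess may come from the shared WT libraries, which cannot be split between comparisons. Changes per gene in Flt3-ITD and DM correlated with r = 0.766 and covariance 0.174 (simulated 0.498 and 0.0360), those in Npm1c and DM with r = 0.222 and covariance 0.0448 (simulated 0.501 and 0.0362), and those in neutrophils and DM with r = 0.492 and covariance 0.248 (simulated 0.502 and 0.0366). All simulated libraries had the same spread, so comparisons that share WT give a simulated r near 0.5 by construction. In the data the H3K27ac lists of WT shared 0.813 with each other and those of DM 0.614. The simulated r is therefore no yardstick, and the simulated covariance rests on the same equal spread. Irf8, Mef2c, Ifitm2, Rasa4 and Upk3bl, risen in Flt3-ITD, were among the 10 of its 11 called genes that also rose in DM. Specific to DM, with no peak in any single-mutant library, were 991 (27.2%) of the gained H3K27ac regions, 4016 (37.2%) for H3K4me1 and 1665 (31.7%) for H3K4me3. Lost in DM alone, with a peak in every single-mutant library, were 1023 (32.3%), 8128 (32.8%) and 1517 (43.9%). For H3K27ac the 991 became 5299 without DM replicate 2, and the 1023 became 1761 without DM replicate 1, 1827 without Flt3-ITD replicate 1 and 536 when at least 50% of a region had to be covered. The 4016 became 8040, 7164 or 6349 without DM replicate 1, DM replicate 2 or Flt3-ITD replicate 1, the 1665 became 4296 or 2627 without DM replicate 1 or Flt3-ITD replicate 2, and the 1517 became 2412 or 2436 without DM replicate 2 or Flt3-ITD replicate 1.

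More distal sites with H3K4me1 in WT gained or lost H3K27ac than arose de novo. The de novo rule asks for 2 marks to change at once and the others for 1, so this order rests partly on the definitions. Of 199848 H3K4me1 regions 138205 overlapped no H3K4me3 peak and were taken as distal. In Npm1c 638 of them were activated, near Fut8, Irf1, Mc2r and the cell cycle inhibitor gene Cdkn1b among others, 5 arose de novo and 8 were inactivated. In Flt3-ITD the counts were 280, 8 and 148. In DM 362 were activated, with 2 each near Cxcr4, Foxp1, H2-Ab1, Irf1 and Map3k1, 23 arose de novo and 346 were inactivated, with 2 each near Aqp1, Ccnd3, Cldn13 and Fcnb. Crossed splits gave at most 46 activated, 1 de novo and 44 inactivated sites. The 8 sites inactivated in Npm1c lay below the crossed splits of that comparison (20 to 44), so they show no loss beyond replicate disagreement. Of the 362 sites activated in DM 135 were activated in Flt3-ITD, against 41.5 for independent lists among sites in the same WT state and at most 81 in simulated unchanged groups that share the WT libraries, and 111 in Npm1c (94.5 and 83). Of the 346 inactivated 132 were inactivated in Flt3-ITD (24.0 and 27). The 8 sites inactivated in Npm1c were all inactivated in DM, against 1.30 for independent lists. Simulated unchanged groups shared up to 28, which is no yardstick here. Simulated lists were not held to the observed sizes, for these 8 sites or for the other sites above. Only the values for independent lists take list size into account. These named genes were chosen after the values were seen, by the number of sites nearest to them. Ties were taken in alphabetical order, so genes later in the alphabet may have 2 sites as well. With at least 50% coverage required the DM counts were 73, 2 and 85; without DM replicate 2 there were 1070 activated and 113 de novo sites, without WT replicate 2 36 de novo sites and without DM replicate 1 598 inactivated ones. In Npm1c, sites activated, de novo and inactivated numbered 1071, 16 and 74 without Npm1c replicate 1 and 1280, 48 and 32 without Npm1c replicate 2, with 15 or 10 de novo and 23 inactivated without WT replicate 1 or WT replicate 2. In Flt3-ITD there were 544 activated and 13 de novo without Flt3-ITD replicate 1 and 499, 25 and 275 without Flt3-ITD replicate 2, with 223 or 253 inactivated without WT replicate 1 or WT replicate 2 and 14 de novo without the latter.

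Neutrophils gave the reference for a mature cell. The calprotectin genes S100a8 and S100a9 had no H3K27ac peak in any HSPC group and 5.64 ± 0.0311 and 5.88 ± 0.216 kb in neutrophils (limma, Benjamini-Hochberg adjusted p = 1.39e-05 each), the granule gene Ngp rose from 0.115 ± 0.163 to 6.33 ± 0.199 kb (log2 3.50), and Itgb2l had 0 and 3.99 ± 0.306 kb. Of 21 mature neutrophil genes 19 rose (20 over the list alone, median 2.14, camera, Benjamini-Hochberg adjusted p = 7.05e-19). Of these 21 genes 10 had no peak in any HSPC group and entered the test only through the neutrophil libraries. Their rise was set by that filter, so the count and the camera p are no independent support. The kinase gene Prkcb (0 to 11.8 ± 0.655 kb), Crispld2, Jazf1, Creb5, Rab20 and the granulocyte factor gene Cebpe (0 to 3.52 ± 0.464 kb) gained peaks. Zfpm1 fell from 13 ± 0.556 to 0.256 ± 0.0537 kb (-4.16), Rftn1 from 7.56 ± 0.0523 to 0.102 ± 0.145 kb (-3.76), and Car2 (9.33 ± 0.680 kb), Hs6st1 (8.39 ± 0.165 kb), Gfi1b, Mpo (2.99 ± 0.0113 kb) and Myc (2.99 ± 0.0523 kb) went to 0 kb. Erythroid genes had 15 falls in 16 (median -1.86, adjusted p = 6.55e-07), stem and progenitor genes 10 falls and 2 rises in 21, HOX genes 7 falls and 1 rise in 17, and housekeeping genes 5 falls in 15 (median -0.14). In all 1805 genes rose and 3160 fell (median gene -0.12; 2755 and 2909 after centring), and 7898 regions were gained and 4463 lost (crossed splits up to 92). Without WT replicate 1, WT replicate 2, neutrophil replicate 1 or neutrophil replicate 2 the count of genes was 2554, 2560, 2617 or 2416, and with random peaks 2064.

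H3K4me1 in neutrophils rose at 812 and fell at 3234 genes (2221 and 2390 after centring; median gene -0.16), most at Ceacam10 (0 to 8.10 ± 0.696 kb), Hsd17b2 and Mmrn2 and at the small GTPase gene Rab27b (22.5 ± 2.12 to 0 kb) and Khdrbs3. 17380 regions were gained and 30264 lost (crossed splits up to 1783), and 591 distal sites were activated, 147 arose de novo (233 without neutrophil replicate 1) and 609 were inactivated. Mature neutrophil genes had 4 H3K4me1 rises in 24 (median 0.80; camera, Benjamini-Hochberg adjusted p = 1.89e-06). H3K4me3 rose at 1084 and fell at 1593 genes, with Ceacam10, Tnfrsf8 and the granule gene Olfm4 up most and Lmx1b, Hoxd3 and Rhag down most; 6502 regions were gained and 5885 lost (crossed splits up to 172), and B-lymphoid genes had 8 falls in 17 (-1.02, adjusted p = 0.0161). Without WT replicate 1, WT replicate 2, neutrophil replicate 1 or neutrophil replicate 2 the H3K4me1 count of genes was 2600, 2250, 2551 or 2613, and Tnfrsf8 lost its call. Without neutrophil replicate 1 Hsd17b2 lost its call too, and Hoxd3 did without neutrophil replicate 1 or neutrophil replicate 2.

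Regions lost in DM were largely regions that neutrophils lack as well, and so were those lost in Flt3-ITD. Of 3170 H3K27ac regions lost in DM, 2817 (88.9%) were lost in neutrophils, against 292 for independent lists and 289 in simulated unchanged groups; the shares were 68.5% of 24774 for H3K4me1 (16978; 3752 and 2400) and 78.1% of 3453 for H3K4me3 (2697; 349 and 234). Of the regions lost in Flt3-ITD neutrophils lacked 89.2% of 1171 for H3K27ac, 71.2% of 8664 for H3K4me1 and 57.1% of 483 for H3K4me3, so this is not a trait of DM alone. Of those lost in Npm1c they lacked 48.4% of 95, 46.9% of 5085 and 43.7% of 359. Among H3K27ac regions kept in DM, 10.1% were absent from neutrophils. Over all genes the changes in DM and neutrophils correlated with r = 0.401 for H3K4me1 and 0.466 for H3K4me3. The H3K27ac value is given above. Simulated values of 0.499 and 0.498 follow from the equal spread of the simulated libraries and are no yardstick for r. The covariance, simulated with the same equal spread, was higher than simulated in each mark. It was 0.203 against 0.0587 for H3K4me1 and 0.156 against 0.0383 for H3K4me3. Changes particular to 1 group lower r, so r alone does not show that no change is shared. Gains were shared less, with 914 of 3645 (595 and 404). Car2, Gfi1b and Ank1 fell in DM and in neutrophils, as did 620 of the 822 genes that fell in DM (191 for independent lists). Simulated unchanged groups shared 0 such genes, but unchanged genes are rarely called after adjustment, so that value is no yardstick. Of the 346 sites inactivated in DM 305 were inactivated in neutrophils. Independent lists among sites in the same WT state gave 98.9 and simulated groups at most 51. Simulated lists were not held to the observed sizes, here or for the regions above. Mgll and Rftn1 differed, Mgll keeping 7.15 ± 0.0481 kb in neutrophils and Rftn1 9.13 ± 2.64 kb in DM. Part of this overlap may come from the shared WT libraries. H3K27ac at S100a8, S100a9 and Itgb2l stayed at 0 kb in DM.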

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

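Of the tests in this part, the one of peak width over regions shared by all 10 libraries was written before its result was seen; the others were chosen afterwards. The interaction term differed from 0 at 582 genes for H3K4me1, 926 for H3K4me3 and 2452 for H3K27ac (limma, Benjamini-Hochberg), and after centring at 172, 926 and 539. At the genes called both ways the effect of Flt3-ITD differed with and without Npm1c. For H3K27ac 7 gene lists passed by camera with the preset correlation. The median log2 interactions were -1.18 for HOX genes, -1.65 for stem and progenitor genes, -1.40 for erythroid genes, -1.30 for megakaryocyte genes, and 0.22 for dendritic cell genes, against a general shift of -0.46. After centring they were -0.67, -1.14, -0.89, -0.79 and 0.73. The mature neutrophil and the monocyte and macrophage lists had medians of 0, and no interaction is read from either. Of the 21 mature neutrophil genes 10 had no peak in any HSPC group and cannot follow a general shift. This held for 1 of the 11 monocyte and macrophage genes, and that list did not pass with centring. The HOX list did not pass without DM replicate 1 (camera adjusted p = 0.0654), the megakaryocyte list without Npm1c replicate 1, DM replicate 1 or DM replicate 2 (0.126, 0.430 and 0.122) or with the widest peaks (0.193) or the gene span without extension (0.334), and the monocyte and macrophage list without Npm1c replicate 1 (0.0505). With centring the dendritic cell list (camera adjusted p = 0.106) and the monocyte and macrophage list (0.309) did not pass, nor did they with random peaks (0.115 and 0.216), where the mature neutrophil list did not either (0.280). Outside the chromosomes used, neutrophils had 26.5 ± 4.95 H3K4me3 peaks on unplaced contigs against 12.5 ± 2.12 in WT HSPC, and Npm1c had 7 ± 0 H3K27ac peaks there against 5 ± 0; these contigs enter no comparison, and the differences were not tested.

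The median gene shifted up by 0.36 for H3K27ac in Npm1c, where 2412 of 13633 genes passed, which lowers the interaction as well. The 15 housekeeping genes had a median change of 0.33, close to the median of all genes, and in regions called in all 10 libraries the lower Npm1c library had 24.3% more base pairs per region than the higher WT library. A candidate explanation is therefore that peaks were called wider throughout the Npm1c libraries; depth, which is unknown, and a general gain of H3K27ac cannot be separated by peak coordinates. This leaves the HOX genes unexplained, because their median was 1.78 after each library was centred.

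H3K27ac was lost at erythroid genes in DM. A short list in DM replicate 2 is excluded as the cause, since the median without that library was -1.63. Mature neutrophils among the DM cells were looked for in the mature neutrophil list, which had a median change of 0 in DM and of 2.14 in neutrophils. Of its 21 genes 10 had no peak in any HSPC group, and after centring 4 rose and 0 fell in DM. These values argue against neutrophils as the bulk of the DM cells. A small share could leave no called peak and is not excluded. The erythroid list was lower in all 3 marks, with medians of -1.73 for H3K27ac, -1.19 for H3K4me1 and -0.79 for H3K4me3. The megakaryocyte list was lower for H3K4me1 (median -0.66) and H3K4me3 (-0.50) but did not pass for H3K27ac (-0.26; camera adjusted p = 0.0861). Fewer erythroid and megakaryocyte progenitors among the lineage-negative DM cells therefore stay open as a cause, as does lower marking within such cells; peak lists of mixed cells do not separate the 2.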

How the results depend on the processing

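Random peaks, the gene span without extension, robust eBayes and the spread floor were chosen after seeing the data. Grouping of the lists by genotype kept its direction and passed in all 31 alternatives run. Of 424 results for H3K27ac gene lists under alternatives, 389 kept direction and side of the threshold and 35 no longer passed. Only lists that passed in the main fit with the preset correlation were followed. The estimated correlation was not among these alternatives, and with it no list passed. Of 216 counts of called genes 133 stayed within 1.5 times the value reported and 83 did not, and of 114 counts of regions 78 and 36. The interaction counts stayed within that range in 29 of 48 cases. A window from 10 kb before to 10 kb after the transcription start was planned and not run, because the gene table used gave no strand. Depth per library is unknown, so weak peaks missed in a shallow library cannot be told from absent ones. Replicate numbers did not pair the samples: 0, 1 and 1 of 10 pairs of groups had correlated residuals above 0.1 for H3K4me1, H3K4me3 and H3K27ac (highest 0.0705, 0.104 and 0.278). Of the called genes that the naming rule took, those reversed in sign numbered 2 in Npm1c, 3 in DM against Npm1c and 3 in the interaction with random peaks, and 1 in DM against Npm1c and 1 in neutrophils with the gene span without extension, all for H3K27ac. Values that moved further follow, by setting. Counts of regions rise without a library because fewer libraries then have to show the state. Apart from that the cause was not tested.

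With at least 50% of a region covered, regions lost in DM alone numbered 536 for H3K27ac. Distal sites activated numbered 239 in Npm1c, 63 in Flt3-ITD, 73 in DM, 122 in neutrophils. Distal sites de novo numbered 2 in Npm1c, 2 in Flt3-ITD, 2 in DM, 21 in neutrophils. Distal sites inactivated numbered 4 in Npm1c, 44 in Flt3-ITD, 85 in DM, 147 in neutrophils. With lists of equal length made of the widest H3K27ac peaks, distal sites activated numbered 350 in Npm1c. Distal sites de novo numbered 2 in Npm1c, 4 in Flt3-ITD. Distal sites inactivated numbered 29 in Npm1c. Genes called for H3K27ac numbered 1093 in Npm1c, 9 in Flt3-ITD. The H3K27ac lists that no longer passed were megakaryocyte in DM against Npm1c (median -1.28, camera adjusted p = 0.0681), megakaryocyte in the interaction (median -1.04, camera adjusted p = 0.193). H3K27ac regions differing numbered 1710 in Npm1c. With lists of equal length drawn at random, regions lost in DM alone numbered 3288 for H3K4me1, 846 for H3K4me3, 551 for H3K27ac. Distal sites activated numbered 277 in Npm1c, 158 in Flt3-ITD, 202 in DM, 309 in neutrophils. Distal sites de novo numbered 13 in Npm1c, 14 in Flt3-ITD. Distal sites inactivated numbered 102 in Npm1c. Genes called for H3K27ac numbered 208 in Npm1c, 1 in Flt3-ITD, 604 in DM, 2064 in neutrophils, 1237 in DM against Npm1c, 91 in DM against Flt3-ITD, 81 in the interaction. Genes called for H3K4me1 numbered 35 in Npm1c, 104 in Flt3-ITD, 1003 in DM, 2355 in neutrophils, 1248 in DM against Npm1c, 335 in DM against Flt3-ITD, 208 in the interaction. Genes called for H3K4me3 numbered 289 in Flt3-ITD, 593 in DM, 1058 in neutrophils, 659 in DM against Npm1c, 558 in DM against Flt3-ITD, 551 in the interaction. The H3K27ac lists that no longer passed were mature neutrophil in Npm1c (median 0, camera adjusted p = 0.947), AP-1 and immediate early in Npm1c (median 0.13, camera adjusted p = 0.732), megakaryocyte in Flt3-ITD (median -0.0729, camera adjusted p = 0.222), mature neutrophil in DM against Npm1c (median 0, camera adjusted p = 0.513), stem and progenitor in DM against Flt3-ITD (median -0.60, camera adjusted p = 0.126), mature neutrophil in DM against Flt3-ITD (median 0, camera adjusted p = 0.0823), mature neutrophil in the interaction (median 0, camera adjusted p = 0.280), monocyte and macrophage in the interaction (median 0.24, camera adjusted p = 0.216), dendritic cell in the interaction (median 0.20, camera adjusted p = 0.115). Of the genes named in the text, reversed in sign was Dusp5 (-0.0433, 0.59 before). With centring on the median, genes called for H3K27ac numbered 83 in Npm1c, 180 in Flt3-ITD, 3055 in DM, 800 in DM against Flt3-ITD, 539 in the interaction. Genes called for H3K4me1 numbered 0 in Npm1c, 189 in Flt3-ITD, 879 in DM against Flt3-ITD, 172 in the interaction. The H3K27ac lists that no longer passed were megakaryocyte in Flt3-ITD (median -0.14, camera adjusted p = 0.132), mature neutrophil in DM against Flt3-ITD (median 0.11, camera adjusted p = 0.0551), monocyte and macrophage in the interaction (median 0.51, camera adjusted p = 0.309), dendritic cell in the interaction (median 0.73, camera adjusted p = 0.106). With the replicate number as a block, genes called for H3K27ac numbered 1395 in Npm1c, 1 in Flt3-ITD, 187 in DM against Flt3-ITD, 1378 in the interaction. Genes called for H3K4me1 numbered 196 in Flt3-ITD. With robust eBayes, genes called for H3K27ac numbered 8 in Flt3-ITD. Genes called for H3K4me1 numbered 0 in Npm1c, 62 in Flt3-ITD, 190 in the interaction. With the gene span without extension, genes called for H3K27ac numbered 68 in Flt3-ITD. Genes called for H3K4me1 numbered 153 in Npm1c. The H3K27ac lists that no longer passed were AP-1 and immediate early in Npm1c (median 0.42, camera adjusted p = 0.462), megakaryocyte in DM against Npm1c (median -1.04, camera adjusted p = 0.0716), megakaryocyte in the interaction (median -0.91, camera adjusted p = 0.334). With a spread floor of 1 peak, genes called for H3K4me1 numbered 0 in Npm1c, 86 in Flt3-ITD, 223 in the interaction. Genes called for H3K4me3 numbered 2131 in DM, 2040 in DM against Npm1c, 443 in the interaction. With a pseudocount of 2000 bp, genes called for H3K27ac numbered 0 in Flt3-ITD, 192 in DM against Flt3-ITD. The H3K27ac lists that no longer passed were megakaryocyte in the interaction (median -0.60, camera adjusted p = 0.0744). With genes covered in at least 1 library, the H3K27ac lists that no longer passed were megakaryocyte in the interaction (median -1.10, camera adjusted p = 0.0532).

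Leave-one-out gave these ranges, where a lone library is assumed to vary like the other groups. Regions gained in DM alone numbered 4097 to 8040 for H3K4me1, 1679 to 4296 for H3K4me3, 993 to 5299 for H3K27ac. Regions lost in DM alone numbered 1551 to 2436 for H3K4me3, 1039 to 1827 for H3K27ac. Distal sites activated numbered 778 to 1280 in Npm1c, 354 to 544 in Flt3-ITD, 412 to 1070 in DM. Distal sites de novo numbered 10 to 48 in Npm1c, 11 to 25 in Flt3-ITD, 31 to 113 in DM, 190 to 233 in neutrophils. Distal sites inactivated numbered 23 to 74 in Npm1c, 179 to 275 in Flt3-ITD, 353 to 598 in DM. Genes called for H3K27ac numbered 5 to 1252 in Npm1c, 0 to 7 in Flt3-ITD, 213 to 2713 in DM, 2416 to 2617 in neutrophils, 33 to 6131 in the interaction, 2648 to 6631 in DM against Npm1c, 88 to 1751 in DM against Flt3-ITD. Genes called for H3K4me1 numbered 128 to 1459 in Npm1c, 251 to 445 in Flt3-ITD, 1550 to 2114 in DM, 2250 to 2613 in neutrophils, 495 to 1526 in the interaction, 1525 to 3511 in DM against Npm1c, 908 to 1246 in DM against Flt3-ITD. Genes called for H3K4me3 numbered 474 to 1038 in Npm1c, 719 to 986 in Flt3-ITD, 1197 to 1745 in the interaction. Medians of H3K27ac lists were AP-1 and immediate early in Npm1c 0.42 to 0.59 (not passing without Npm1c replicate 2 with camera adjusted p = 0.283), stem and progenitor in Flt3-ITD 0.36 to 0.60 (not passing without Flt3-ITD replicate 2 with camera adjusted p = 0.179), megakaryocyte in Flt3-ITD -0.0286 to 0.0589 (not passing without WT replicate 2 with camera adjusted p = 0.0733, without Flt3-ITD replicate 1 with camera adjusted p = 0.292), AP-1 and immediate early in DM 0.28 to 0.34 (not passing without DM replicate 2 with camera adjusted p = 0.104), HOX cluster and HOX cofactor in the interaction -1.35 to -1.01 (not passing without DM replicate 1 with camera adjusted p = 0.0654), monocyte and macrophage in the interaction -0.40 to 0.27 (not passing without Npm1c replicate 1 with camera adjusted p = 0.0505), megakaryocyte in the interaction -1.39 to -0.95 (not passing without Npm1c replicate 1 with camera adjusted p = 0.126, without DM replicate 1 with camera adjusted p = 0.430, without DM replicate 2 with camera adjusted p = 0.122), megakaryocyte in DM against Npm1c -1.42 to -1.24 (not passing without DM replicate 1 with camera adjusted p = 0.160), stem and progenitor in DM against Flt3-ITD -1.01 to -0.18 (not passing without DM replicate 2 with camera adjusted p = 0.0682), mature neutrophil in DM against Flt3-ITD 0 to 0 (not passing without Flt3-ITD replicate 2 with camera adjusted p = 0.137, without DM replicate 2 with camera adjusted p = 0.397), monocyte and macrophage in DM against Flt3-ITD 0.044 to 1.14 (not passing without Flt3-ITD replicate 2 with camera adjusted p = 0.0515). H3K27ac regions differing numbered 4782 to 9612 in Npm1c, 4286 to 6612 in Flt3-ITD, 7881 to 13669 in DM, 9436 to 14035 in DM against Npm1c, 4215 to 8064 in DM against Flt3-ITD. H3K4me1 regions differing numbered 15609 to 31175 in Npm1c, 24473 to 30572 in Flt3-ITD, 41570 to 56336 in DM against Npm1c, 28432 to 34691 in DM against Flt3-ITD. H3K4me3 regions differing numbered 3485 to 7645 in Npm1c, 5553 to 7835 in Flt3-ITD, 10436 to 15415 in DM against Npm1c, 6761 to 9430 in DM against Flt3-ITD.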

Other observations

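Values in this part were chosen after the results were seen, and all its tests were as well. Of the genes called in 2 marks in DM most moved the same way, 195 of 214 for H3K4me3 and H3K27ac and 218 of 261 for H3K4me1 and H3K4me3, but these are a minority of the 1317 genes called for H3K4me3, 1768 for H3K27ac and 3151 for H3K4me1. The Hoxd cluster, which had no H3K27ac in any group, carried 12.7 kb of H3K4me3 in WT, 6.17 ± 2.17 kb in DM and 5.23 kb in neutrophils, and the Hoxa cluster kept 18.3 ± 0.693 kb in DM. Sites that arose de novo in Npm1c lay nearest to Arhgap15, Kdm2b, Mbp, Mrm1 and Smc1a.

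The share of H3K4me1 peaks on the X chromosome was 1.63 ± 0.0371% in WT, 1.30 ± 0.311% in Npm1c, 1.00 ± 0.0160% in Flt3-ITD, 1.45 ± 0.195% in DM and 1.53 ± 0.0386% in neutrophils (permutation p = 0.0667 over all pairings of 10 libraries). Of 2438 X regions called in any WT or Flt3-ITD library 457 (18.7%) were lost in Flt3-ITD, against 5.24% on autosomes. The libraries of DM, read here as carrying Flt3-ITD, had 1.58% and 1.31%, and those of Npm1c, without it, 1.08% and 1.52%, with 6.28% of X regions lost in Npm1c against 3.30% on autosomes. A low share thus did not follow Flt3-ITD library by library. The Flt3-ITD list that was longer than a WT list still had a share of 0.991%, so list length alone is excluded as the cause. Each H3K4me3 and H3K27ac library of both groups had a peak at no fewer than 3 of the Y genes Kdm5d, Eif2s3y, Uty and Ddx3y. This excludes libraries of female mice only in those marks, but not pools of mixed sex. For H3K4me1 no WT, Npm1c or Flt3-ITD library had a peak at these 4 genes, nor had DM replicate 2. DM replicate 1 had peaks at 2 of them and both neutrophil libraries at 3. A difference in the mice used for H3K4me1 stays open, and no biological explanation was tested.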
